A study of Mus musculus with 11 samples.

How the data were processed

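RNA from mouse embryonic stem cell cultures was hybridised to 11 single-colour (Cy3) Agilent mouse miRNA arrays, 1 per culture sample. An Ascl1 transgene in these cells is repressed by doxycycline (Dox), so the transgene was expressed where Dox was left out. Per the labels, 5 arrays held Ascl1 cells with Dox and 5 held Ascl1 cells without Dox, at days 3, 5, 7, 10 and 14, and 1 array held cells labelled MC1 with Dox at day 3. The labels give every array the same replicate number, so each group had 1 array per day, and the day pairs an array with Dox to an array without Dox.

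The authors scanned the arrays and read them with Agilent Feature Extraction 11.5.1.1 on grid design 046065, per the file headers. The deposited scanner files give a linear intensity per spot, from which Feature Extraction had subtracted a background with spatial detrending and which was not scaled between arrays, per the file headers. The flags that the deposited scanner files carry per spot (well above background, outlier, saturated) and per miRNA (detected) were used as they stood. The authors also deposited a table of intensity per probe on a linear scale. Their scaling is not stated. Its 75th percentiles lay between 25.3 and 26.4 on every array, and its log values correlated at 0.953 to 1.00 across probes with the scanner signal.

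Each array had 52044 spots, of which 49880 carried miRNA probes (3105 probes for 1247 miRNA names, with 10 to 40 spots each). Control spots and outlier spots (3.80% to 6.73% of miRNA spots per array) were left out, and no miRNA spot was saturated. Names were taken from the systematic name in the scanner files. The other spots of a probe were averaged. Arrays were scaled by the 75th percentile over the 390 probes above background on all 11 arrays, signals under a floor of 30.3 were set to the floor, and the values were put on a log2 scale. The floor was the median over arrays of the 5th percentile of scaled signals above background. A probe was above background when more than 0.5 of its spots were flagged so, and each miRNA was represented by its brightest probe by mean over arrays. A fold against a floored signal is a lower bound, and a level was never compared between probes. miRNAs above background on at least 3 of the 10 Ascl1 arrays were tested (434 miRNAs). The number of arrays limited the precision. The arrays carried no spike-in that would give an absolute amount, so each difference is relative to the probes used for scaling. Probe sequences were not used here, so base composition was not checked, and no coordinates are given.

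The tests used limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8) for reading, and Benjamini-Hochberg adjustment over the 434 miRNAs at 0.05. The Dox effect was fitted as without Dox minus with Dox, with day as a block (4 residual degrees of freedom). The Dox by day interaction was fitted on centred day with the same block (3 residual degrees of freedom), and the day slopes with a separate line for each Dox state and a shared spread (6 residual degrees of freedom). The p-values measure only the spread between these samples, which are days of culture with 1 array each. On each day the array with Dox lay in row 2 of its slide and the array without Dox in row 1. The day 3 pair lay on 1 slide, the pairs of days 5 to 14 on another, and the MC1 array on the third. In both Dox states the arrays of days 5, 7, 10 and 14 lay in columns 1, 2, 3 and 4 of their slide. Day and slide column cannot be told apart among them. Day pairing comes from the labels. The log2 signals of the day 3, day 5, day 7, day 10 and day 14 pairs correlated at 0.985, 0.981, 0.935, 0.807 and 0.883 across miRNAs.

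The tests, their alternatives, the rule for named miRNAs and 16 lists of miRNAs were fixed before the data were examined. The lists were matched on the stem with either arm, and 13 of them had at least 3 tested members. They were the miR-290-295 cluster, the miR-302 and miR-367 cluster, neuron-enriched miRNAs, the let-7 family, the miR-17-92 and paralog clusters, the epithelial miR-200 family with miR-203 and miR-205, the miR-34 and miR-449 family, mesenchymal and fibroblast miRNAs, glial miRNAs, the sensory miR-183, miR-96 and miR-182 cluster, neuroendocrine miRNAs, the Dlk1-Dio3 imprinted cluster and the Sfmbt2 intron cluster. Muscle, blood and endothelial, and endoderm and liver miRNAs had too few tested members for a list test. List shifts were tested with camera from limma at a preset correlation of 0.01, which compares a list with the other miRNAs, and again with an estimated correlation. They were also tested with fry, which asks whether the members of a list move, on balance, one way, without comparing them with other miRNAs. List tests of the interaction were added after the data were seen. Single days and the MC1 array had no replicate and no test, and miRNAs were counted there at a log2 difference of at least 1. Lists in the MC1 comparison were placed among 10000 random lists of the same size matched on brightness.

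Named miRNAs were, for the Dox effect and the slopes, those of largest estimate past the threshold, together with miR-9, miR-124, miR-294-3p, miR-302a-3p, the let-7 members and the members of each list with the largest estimates. For single days they were the 3 highest and 3 lowest differences, and for MC1 the 5 highest and 5 lowest. The rule named 91 miRNAs for the Dox effect and the slopes.

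The fits were tested on simulated data with 100 of 434 miRNAs changed. At log2 sizes of 1, 2 and 4 the Dox effect was recovered for 64.7%, 97.0% and 100% of changed miRNAs, with 5 false calls. The simulated Dox change was the same on every day, with independent noise. A difference that grows with day widens the spread of the Dox fit, so this recovery does not hold for it. At 0.2, 0.4 and 0.8 per day the recovery was 76.5%, 90.9% and 100% for the interaction (1 false call), 70.6%, 84.8% and 97.0% for the slope without Dox (3 false calls), and 70.6%, 90.9% and 100% for the slope with Dox (2 false calls). Known scaling factors were undone without remainder, which the scaling ensures by construction, and of the lists only the 1 that had been shifted was called. The simulated miRNAs varied independently. Members of real lists moved together, with an estimated correlation of 0.81 (Dox effect) and 0.96 (slopes) for the miR-290-295 cluster. The simulation thus does not show how often real lists are called by chance.

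Alternatives covered the scaling (the 75th percentile over all miRNA probes, quantile normalization), the signal (normexp background correction with an offset of 50, the scanner's total signal per miRNA, the authors' table, the mean of all probes), the floor, the detection filter, a variance trend, the day block, the slide, the time scale, the list test and each day pair left out. The files hold no mean spot signal, so normexp was run on the median spot signal. The scanner's own detection flag, and leaving out days 5 and 10 together, were added after the data were seen. Scaling over all miRNA probes moved the median Dox estimate over the tested miRNAs from 0.13 to -0.05 (log2).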

Results

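Mature microRNAs (miRNAs) were measured in mouse embryonic stem cells (ESCs) taken through neural differentiation. The cells carried a transgene for Ascl1, a proneural transcription factor, which was expressed when doxycycline (Dox) was left out and repressed when Dox was present. There were 5 arrays with Dox and 5 without, at days 3, 5, 7, 10 and 14, and 1 array of cells labelled MC1, with Dox, at day 3. Between 270 miRNAs (MC1) and 419 miRNAs (without Dox, day 14) were above background per array. With Dox, 333, 364, 317, 360 and 354 miRNAs were above background on days 3, 5, 7, 10 and 14, and without Dox 291, 354, 397, 400 and 419 were. Ascl1 mRNA was not measured by these arrays, so the Dox labels were not checked against the transgene.

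The comparison of cells without and with Dox asked how miRNA levels differed when the transgene was expressed. miR-124-3p, a miRNA of neurons, had scaled signals of 33.8, 64.2, 427, 1029.9 and 1632 without Dox on days 3, 5, 7, 10 and 14, and stayed between 30.3 and 93.6 with Dox. The 33.8 was not above background, since the lowest signal above background on that array was 49.1. miR-375-3p, known from neuroendocrine and islet cells, reached 361, 1100.2, 372 and 149.9 without Dox on days 5, 7, 10 and 14 and lay at the floor of 30.3 on all 5 days with Dox, where it was above background on 1 array. miR-294-3p, an abundant ESC miRNA, went from 12122 on day 3 to 1176 on day 14 without Dox and from 12545 to 2894 with Dox. Over the 5 days the log2 differences without minus with Dox were 2.70 ± 0.91 (SE) for miR-124-3p, 2.94 ± 0.74 for miR-375-3p and -0.74 ± 0.21 for miR-294-3p. They had adjusted p = 0.22, 0.16 and 0.18 by limma. Of the 434 miRNAs tested, 0 passed the threshold by limma (lowest adjusted p = 0.16). At an unadjusted p under 0.05 there were 89, of which 63 were higher and 26 lower without Dox. Of the 434, 54 (12.4%) had the same sign on all 5 days, against 6.25% for independent and even signs. The signs were neither: the differences of days 10 and 14 correlated at 0.816 across miRNAs, and the median estimate was 0.13. The excess is thus no measure of chance. The count depended on the setting: 35 passed (22 higher, 13 lower) among the 228 miRNAs above background on all 10 arrays, and 32 (24 higher, 8 lower) after normexp. The normexp setting changed the background correction and the spot signal together. With the array without Dox always in the same slide row, row and Dox cannot be told apart, and the 4 days that shared a slide gave 0 miRNAs past the threshold by limma (106 at an unadjusted p under 0.05).

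**Figure D1:**
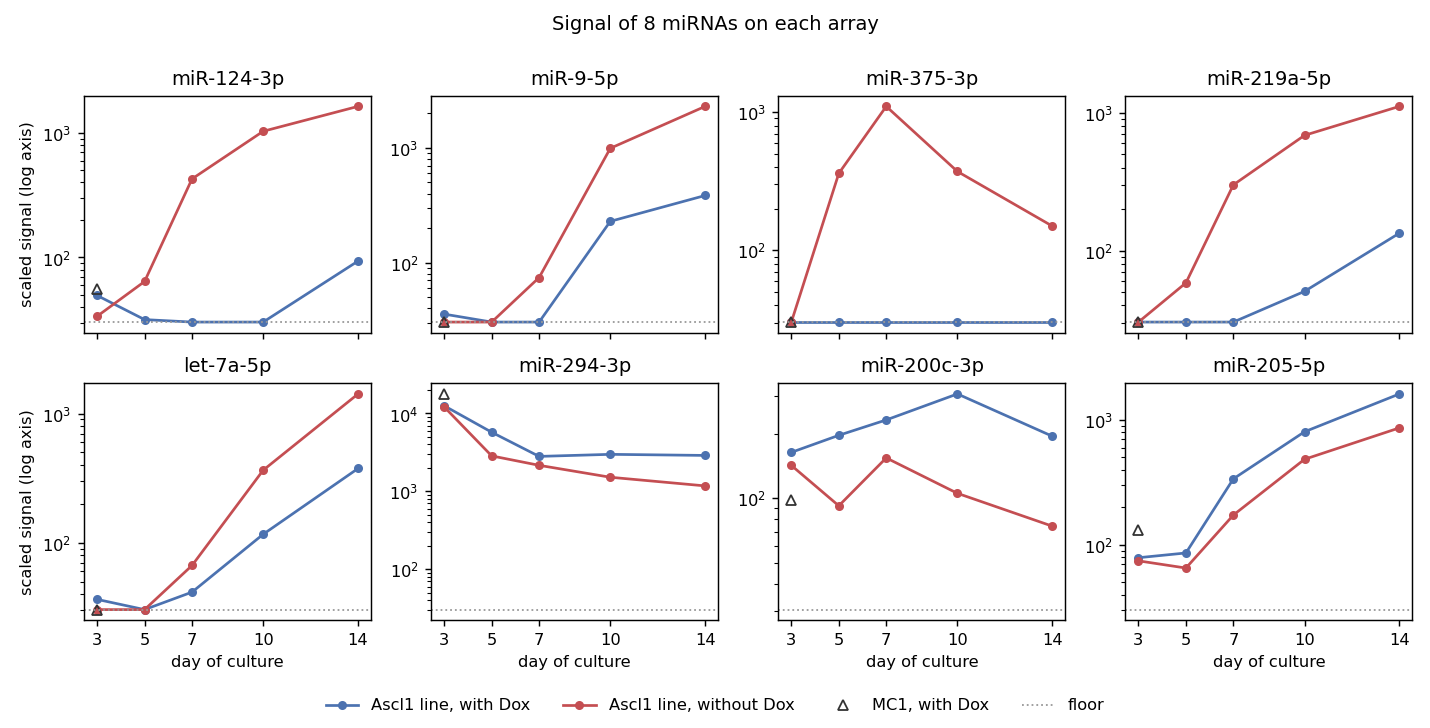
Scaled signal (log axis, floor at 30.3) against day of culture for 8 miRNAs, with 1 point per array, a line for each Dox state and a triangle for MC1. miR-124-3p reached 1632 on day 14 without Dox and 93.6 with Dox, and miR-294-3p lay at 1176 without Dox and 2894 with Dox.

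The miR-290-295 cluster, the main miRNA cluster of mouse ESCs, was lower without Dox as a list, with a median log2 difference of -0.77 over 12 tested members, of which 11 were lower (camera from limma, adjusted p = 2.06e-07, and adjusted p = 0.46 with an estimated correlation). Its medians were -0.01, -1.01, -0.48, -0.99 and -1.17 on days 3, 5, 7, 10 and 14. Among its members, miR-292a-3p differed by -0.84 ± 0.22 (SE) and miR-291a-3p by -0.82 ± 0.19, each lower on all 5 days (limma adjusted p = 0.16 for both). None of the 12 passed over all miRNAs (0), and 9 passed when adjusted over the list alone. The miR-200 family, miRNAs of epithelia, was also lower without Dox, with a median of -0.78 and 6 of 7 members lower (camera adjusted p = 2.96e-05, and adjusted p = 0.46 with an estimated correlation). miR-200c-3p differed by -0.96 ± 0.23 and miR-205-5p, which this list holds beside the family, by -0.62 ± 0.16. In this list 6 members passed when adjusted over the list alone and 0 over all miRNAs. Over the 4 days that shared a slide the medians were -0.95 for the miR-290-295 cluster and -0.92 for the miR-200 family.

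Neuron-enriched miRNAs were higher without Dox as a list, with a median of 0.81 and 19 of 20 members higher (camera adjusted p = 0.0027, and adjusted p = 0.46 with an estimated correlation). The size depended on the setting: the median was 0 without a detection filter and 1.31 with a floor of 1 (camera adjusted p = 0.024 and 3.26e-05). The neuron-enriched median differences were 0.68, 1.59 and 1.62 on days 7, 10 and 14 and 0 on days 3 and 5. The medians of 0 came from members at the floor on both arrays, so they do not show that a difference was absent. After normexp, which sets no floor, the medians were 0.30, 0.25, 0.93, 0.85 and 0.98 on days 3, 5, 7, 10 and 14. miR-153-3p was at least 11.9-fold higher on day 14, against a signal with Dox not well above background, and miR-9-5p differed by 1.15 ± 0.48 over the 5 days. The let-7 family, which rises in many differentiating cells, was higher for 11 of 11 members, with a median of 0.68 (camera adjusted p = 0.012, and adjusted p = 0.46 with an estimated correlation) and day medians of 0.12, 1.21 and 1.92 on days 7, 10 and 14. let-7b-5p was higher on all 5 days, by 0.88 ± 0.21. The miR-17-92 and paralog clusters, known from proliferating cells, were higher for 16 of 17 members, with a median of 0.39 (camera adjusted p = 0.012, and adjusted p = 0.46 with an estimated correlation). The miR-17-92 median was 0.14 with scaling over all miRNA probes (adjusted p = 0.049). The miR-17-92 call was lost after normexp (adjusted p = 0.068) and the let-7 call with a floor of 1 (adjusted p = 0.089). In each of these lists 0 members passed over all miRNAs and 0 when adjusted over the list alone. Within the slide of days 5 to 14 the medians were 0.98, 0.86 and 0.49 for the neuron-enriched, let-7 and miR-17-92 lists.

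The sensory miR-183, miR-96 and miR-182 cluster was lower for 4 of 4 members (median -0.34, camera adjusted p = 0.012) and the miR-34 and miR-449 family for 3 of 4 (median -0.34, camera adjusted p = 0.047). Both had adjusted p = 0.46 with an estimated correlation, and 0 members passed over all miRNAs or adjusted over the list alone. The sensory call was lost without a detection filter (adjusted p = 0.061) and among miRNAs above background on all 10 arrays (adjusted p = 0.11). Without day as a block the let-7 list and the miR-34 and miR-449 list were no longer called, and the latter call was lost in 10 of 17 settings, with a median of -0.04 after normexp and 0 without a detection filter. No shift was called by camera for the miR-302 and miR-367 cluster (median -0.17, adjusted p = 0.34), mesenchymal and fibroblast miRNAs (-0.03, but 0.09 after normexp, adjusted p = 0.11), neuroendocrine miRNAs (0.68, adjusted p = 0.16) or the Sfmbt2 intron cluster (-0.19, adjusted p = 0.095). These depended on the setting. The miR-302 and miR-367 cluster was called lower without day 10 (-0.41, adjusted p = 0.017) and without days 5 and 10 (-0.43, adjusted p = 0.027), and its median was 0.15 without day 14. Neuroendocrine miRNAs were called higher with scaling over all miRNA probes (adjusted p = 0.042), after normexp (adjusted p = 0.029) and with a floor of 1 (adjusted p = 0.018). All tested members of the neuroendocrine list but miR-375-3p were also on the neuron-enriched list, so its calls are not independent of that list. The Sfmbt2 cluster was called lower without day 5 (adjusted p = 0.014), without day 7 (adjusted p = 0.020) and without days 5 and 10 (adjusted p = 0.039), and the mesenchymal list without day 7, 10 or 14 (adjusted p = 0.037, 0.041 and 0.047). For the Dlk1-Dio3 imprinted cluster the camera direction was down (adjusted p = 0.66) while its median was 0.06, which turned to -0.16 with scaling over all miRNA probes, and its mean 0.07. It was called lower without day 7 (median -0.03, adjusted p = 0.020). For glial miRNAs the direction was down (adjusted p = 0.16) and the median -0.32, while the mean was 0.36. In the glial list miR-219a-5p, known from oligodendrocytes, differed by 2.21 ± 0.63, and 1 member was higher and 3 were lower when adjusted over the list alone. In the mesenchymal list 2 members were lower when adjusted over the list alone. The muscle miRNA miR-206-3p reached 90.1 without Dox on day 7, with differences of 1.23 and 1.25 log2 on days 7 and 10, while the endothelial miR-126a-3p reached 40.1 with Dox on day 3 and the endoderm miRNA miR-215-5p 48.3 with Dox on day 14. Of the other endoderm miRNAs, miR-216a-5p and miR-216b-5p reached 65.8 and 38.6 without Dox on day 10, above background on 1 array each. By fry, 0 of the 13 lists moved on balance one way in this comparison.

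**Figure D2:**
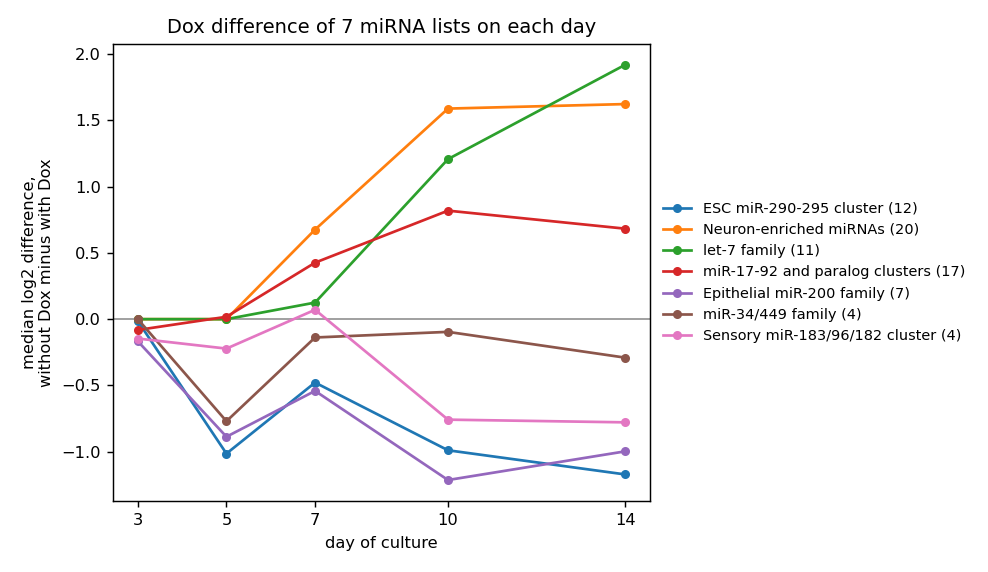
Median log2 difference without minus with Dox against day of culture for the 7 lists called by camera, with 1 line per list and the number of tested members in brackets. The neuron-enriched list had medians of 1.59 and 1.62 on days 10 and 14 and the miR-290-295 cluster -0.99 and -1.17, while under another scaling the sign turned for the miR-200 family on day 3, miR-17-92 on day 5, and the miR-34 and miR-449 and sensory lists on day 7.

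The Dox by day interaction asked whether the difference grew or shrank over the days. The neuron-enriched and let-7 lists had a growing difference, with median interactions of 0.16 and 0.20 log2 per day (camera adjusted p = 0.0034 and 0.013, and adjusted p = 0.68 with an estimated correlation for both). The miR-290-295 cluster (median -0.08 per day, camera adjusted p = 0.00028) and the miR-200 family (-0.07, adjusted p = 0.010) went further down without Dox relative to with Dox, with adjusted p = 0.68 with an estimated correlation for both. The Dlk1-Dio3 (-0.02, adjusted p = 0.0034), sensory (-0.07, adjusted p = 0.043) and Sfmbt2 (-0.07, adjusted p = 0.043) lists were called lower by camera, each again with adjusted p = 0.68 with an estimated correlation. The sensory call was lost in 7 and the Sfmbt2 call in 11 of 17 settings, and the Sfmbt2 median turned to 0.06 among miRNAs above background on all 10 arrays. The Dlk1-Dio3 call was lost without day 14 (adjusted p = 0.47). The let-7 call was lost in 1 of 16 settings (camera adjusted p = 0.054) and the miR-200 call in 1 of 17 (camera adjusted p = 0.073). When adjusted over the list alone, 7 neuron-enriched miRNAs had a growing and 1 a shrinking difference, and of the let-7 family 8 and 1. Over all 434 miRNAs 0 passed by limma (lowest adjusted p = 0.068), with 112 at an unadjusted p under 0.05, 91 positive and 21 negative. After normexp 9 passed.

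The day slopes asked how miRNAs moved along the culture in each Dox state. On the slide of days 5 to 14 the slide column rose with day, so day and column cannot be told apart there. Without Dox, miR-125b-5p rose from 32.1 on day 3 to 6593 on day 14, at 0.71 ± 0.08 log2 per day (SE, limma adjusted p = 0.0031). Its day 3 signal was not above background, since the lowest signal above background on that array was 49.1. miR-9-5p, a miRNA of neural progenitors and neurons, rose at 0.65 ± 0.10 per day (limma adjusted p = 0.0080), let-7a-5p at 0.55 ± 0.06 (limma adjusted p = 0.0031) and miR-124-3p at 0.53 ± 0.09 (limma adjusted p = 0.0083). miR-293-3p of the miR-290-295 cluster fell by 0.28 log2 per day (limma adjusted p = 0.038). In all, 66 miRNAs passed, of which 62 rose and 4 fell. The other 3 that fell were miR-409-3p, miR-543-3p and miR-379-3p, all of the Dlk1-Dio3 cluster. Of 19 settings, the call of miR-379-3p was lost in 15, those of miR-293-3p and miR-409-3p in 8 each and that of miR-543-3p in 7. With Dox, 1 miRNA passed: miR-205-5p, known from stratified epithelium, rose at 0.43 ± 0.06 per day (limma adjusted p = 0.044), from 78.9 to 1610.2. It also rose without Dox (0.37 ± 0.06, limma adjusted p = 0.0083). Of the 66 called without Dox, a set chosen on the slope without Dox, 46 had the same sign with Dox, and 0 passed the test of the difference (the interaction by limma, with 112 of all 434 at an unadjusted p under 0.05). The rest were not all of opposite sign: miR-153-3p and miR-219a-2-3p, above background on no array with Dox, had a slope of 0 there and so no sign. The count of 66 went to 27, 25, 24 and 1 when days 3, 5, 10 or 14 were left out, and to 0 by limma without days 5 and 10 (61 at an unadjusted p under 0.05). Scaling over all miRNA probes gave 29 (23 up, 6 down, 24 of them shared with the 66), quantile normalization 42 up and 7 down and the authors' values 53 up and 12 down, while the call of miR-205-5p with Dox was lost in 8 of 19 settings: when any 1 day was left out, without days 5 and 10, with scaling over all miRNA probes (adjusted p = 0.096) and without a detection filter (adjusted p = 0.21).

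**Figure D3:**
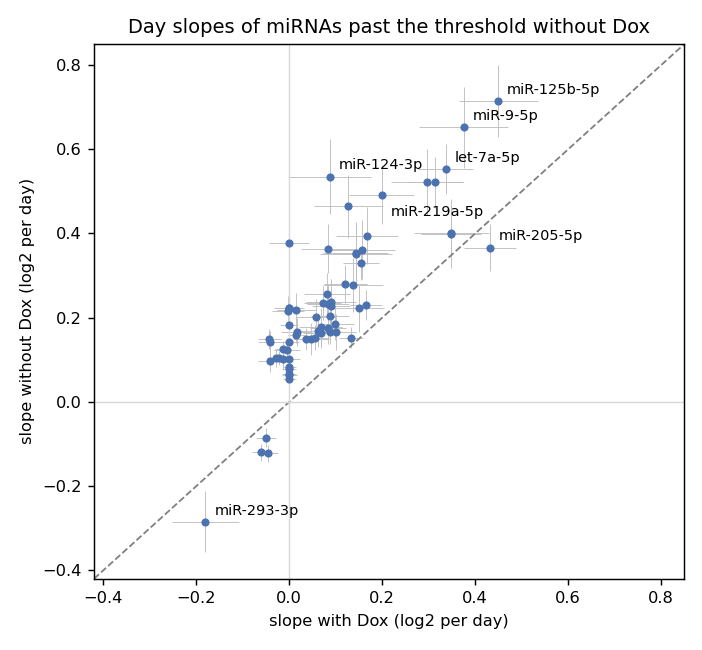
Slope in log2 per day without Dox against slope with Dox, with 1 point for each of the 66 miRNAs past the threshold without Dox, bars of 1 SE and a dashed line where both slopes are equal. miR-125b-5p lay at 0.71 without Dox and 0.45 with Dox, and miR-124-3p at 0.53 and 0.09.

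Without Dox, neuron-enriched miRNAs rose as a list (median 0.19 log2 per day, 16 of 20 positive), with 8 past the threshold over all miRNAs and 11 when adjusted over the list alone. The let-7 family rose (median 0.36), with 6 of 11 past the threshold and 8 adjusted over the list alone, and glial miRNAs rose (median 0.13), with miR-219a-5p and miR-219a-2-3p past the threshold and 3 adjusted over the list alone. These lists had camera adjusted p = 8.68e-05, 0.00051 and 0.0043, and adjusted p = 0.45, 0.55 and 0.55 with an estimated correlation. They also moved on balance one way by fry (adjusted p = 0.0024, 0.0066 and 0.0038). The glial call by camera was lost in 1 of 17 settings (adjusted p = 0.098). The miR-290-295 cluster fell as a list (median -0.25, 12 of 12 negative, camera adjusted p = 8.68e-05, and adjusted p = 0.60 with an estimated correlation), with 1 past the threshold and 6 adjusted over the list alone. The Dlk1-Dio3 cluster fell (median -0.04, 29 of 41 negative, camera adjusted p = 0.00031, and adjusted p = 0.60 with an estimated correlation), with 3 past the threshold and 2 adjusted over the list alone, a call that was lost without day 14. The other 8 lists were not called, and in the mesenchymal list the median was -0.03 while the mean was 0.03.

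With Dox, the let-7 family rose (median 0.14, 10 of 11 positive, camera adjusted p = 6.55e-05), as did the miR-200 family (0.09, 7 of 7, camera adjusted p = 0.00037), glial miRNAs (0.09, 4 of 5, camera adjusted p = 0.011) and the miR-34 and miR-449 family (0.07, 4 of 4, camera adjusted p = 0.032), all with adjusted p = 0.40 with an estimated correlation. The neuron-enriched list was called up by camera (adjusted p = 0.031, and adjusted p = 0.47 with an estimated correlation) with a median of 0 and a mean of 0.07. This call was lost in 6 of 16 settings, and that of the miR-34 and miR-449 family in 8 of 16. The miR-290-295 cluster fell (median -0.17, 11 of 12 negative, camera adjusted p = 0.011, and adjusted p = 0.65 with an estimated correlation). The miR-17-92 and paralog clusters fell too (median -0.07, 16 of 17 negative, camera adjusted p = 0.00095, and adjusted p = 0.56 with an estimated correlation). When adjusted over the list alone, 3 neuron-enriched miRNAs, 3 let-7 miRNAs and 2 miRNAs of the miR-200 list passed. Over all miRNAs 1 passed in all, miR-205-5p, which the miR-200 list holds with miR-203 beside the family. The family members miR-200a-3p, miR-200b-3p, miR-141-3p and miR-200c-3p rose at 0.09, 0.07, 0.04 and 0.03 (limma adjusted p = 0.30, 0.38, 0.67 and 0.80). Of these 7 lists, 0 moved on balance one way by fry, and 2 lists were called by camera without day 3.

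On single days, which had no replicate, the differences between cells without and with Dox were wider from day 7 on: the SD of the log2 differences was 0.42, 0.44, 0.78, 1.23 and 0.94 on days 3, 5, 7, 10 and 14. On day 3, 14 miRNAs were higher and 3 lower without Dox by at least 1 log2 among 348, and the highest, miR-6395, was at least 3.09-fold higher. On day 5, 3 were higher and 12 lower among 376: miR-375-3p was at least 11.9-fold higher, and miR-292a-3p was 2.19-fold and miR-200c-3p 2.13-fold lower. On day 7, 27 were higher and 29 lower among 407, with miR-375-3p at least 36.3-fold and miR-124-3p at least 14.1-fold higher, and miR-351-3p 4.04-fold lower. On day 10, 82 were higher and 52 lower among 431. There miR-124-3p was at least 34.0-fold and miR-3063-3p at least 42.7-fold higher, and miR-6393 was at least 42.6-fold lower. On day 14, 91 were higher and 43 lower among 444, with miR-124-3p 17.4-fold, miR-153-3p at least 11.9-fold and miR-219a-5p 8.31-fold higher, and miR-452-5p at least 5.89-fold lower. Scaling over all miRNA probes gave 8 higher and 4 lower, 1 and 17, 18 and 48, 50 and 67, and 54 and 50 on days 3, 5, 7, 10 and 14. On day 5 the authors' values gave 8 and 8, and on day 14 quantile normalization gave 63 and 58.

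MC1 cells with Dox at day 3 were set beside Ascl1 cells with Dox at day 3, 1 array each, which shows how cells labelled MC1 compared with repressed Ascl1 cells. Members of the miR-290-295 cluster were higher in MC1, with a median log2 difference of 0.56 (0.47 to 0.76 over the scalings) that lay at the 100th percentile of 10000 matched lists, and the miR-302 and miR-367 cluster, miRNAs of primed pluripotent cells, was lower, with a median of -1.13 (-1.19 to -0.78) at a percentile of 0. Neuron-enriched miRNAs had a median of 0.52 (percentile 99.8), with miR-7a-5p 3.41-fold and miR-125b-5p 3.17-fold higher in MC1. miR-466b-3p, of the Sfmbt2 cluster, was 3.49-fold higher, and miR-29b-3p, miR-210-3p and miR-29a-3p were 3.67-fold, 3.32-fold and 3.25-fold lower. The medians of the other lists were -0.32 (percentile 36.0) for the miR-200 family, -0.31 (33.7) for the sensory cluster, -0.19 (40.9) for let-7, -0.14 (53.9) for mesenchymal, -0.11 (65.5) for glial, -0.11 (54.4) for blood and endothelial, -0.09 (85.3) for Sfmbt2, -0.05 (70.8) for miR-17-92 and -0.03 (95.2) for Dlk1-Dio3 miRNAs. The medians of the let-7, miR-17-92, mesenchymal, glial, Dlk1-Dio3 and Sfmbt2 lists changed sign under another scaling. In all, 16 miRNAs were higher and 18 lower in MC1 by at least 1 log2 among 340 (14 and 24 with scaling over all miRNA probes, 27 and 10 with quantile normalization), and r across miRNAs, which are not independent replicates, was 0.956. The matched lists were drawn at random, while members of a cluster or family can move together, so the percentiles do not measure chance. The cells and the slide cannot be told apart here, and no test was possible with 1 array each.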

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

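The counts over other splits of the samples were set before those counts were seen, while the swaps within days for the Dox effect, the unadjusted counts of swaps, the list tests of the interaction and every test of the 3 patterns weighed here were chosen only after the results were seen.

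The neuron-enriched and let-7 lists had a difference between cells without and with Dox that grew with day. Over the 11 members above background on both day 5 arrays the median difference was 0.27, 0.38, 1.57 and 1.71 on days 5, 7, 10 and 14, a rise of 1.44 on the same slide, and 8 of the 11 rose (SD of the rises 1.30). A steady effect of the slide row would leave that difference level, whereas the median rose, though 3 members did not. A row effect that changed along the slide column, which rose with day there, was not tested. Row and Dox thus cannot be told apart from this test. Over all members of both lists the rise was 1.71, and under the other scalings it was smallest after normexp, at 0.82. Part of its size may thus come from the processing, where normexp changed the background correction and the spot signal together. Expression of the transgene stays open as an explanation, and was not tested apart from the slide row.

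The miR-290-295 and miR-200 lists were lower without Dox on days 5 to 14 and near level on day 3. Lists matched on brightness had medians of 0.15 and 0.15 on those days. The medians of both lists (-0.95 and -0.92) lay at the percentiles 0 and 0 of 10000 such lists. Both lists were picked for their shift in these same values, and their members moved together (estimated correlation 0.81 and 0.43). Random lists lack both traits, so the percentiles do not measure chance. They cannot decide whether the slide row gave the shift. Under the other scalings, signals and probe summaries the median of either list on days 5 to 14 that came nearest 0 was -0.56 (with the mean of all probes), which argues against the scaling as the whole cause. The level on day 3 may belong to that slide rather than that day, since its slide held 1 pair of arrays, and day and slide cannot be told apart. A row effect that depends on probe sequence was not tested, and a response to the transgene stays open as a hypothesis.

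miR-6393 and 18 miRNAs that moved with it (r over 0.95 across arrays, a set chosen after the values were seen) were bright on 3 arrays, both arrays of day 5 and the day 10 array with Dox. There miR-6393 had signals of 1983, 2408 and 1292, miR-873b 1464, 1729.5 and 953, and miR-452-5p 1299, 1547 and 795. On the day 14 array with Dox these 3 had weaker signals of 99.7, 93.6 and 179, against 30.3 without Dox on that day. miR-6393 and miR-452-5p, named above for days 10 and 14, are thus of this set. So are miR-466l-3p, miR-466o-3p, miR-669i and miR-669m-3p of the Sfmbt2 list. When the set was chosen again without the day 10 array (21 miRNAs), the ratios to miR-6393 on that array lay a median of 0.18 log2 from those of day 5, and for the 10 that would have missed by over 1 had they not risen the median was 0.13, a test that took the place of 1 whose outcome the choice of the set had fixed. A shared RNA that binds these probes would give this, but so would any common cause that moves them by like factors, so it does not tell these apart. Of the 8 other arms of the same stems on the array, 0 were higher by at least 1 log2 on the 3 arrays, but only 2 were above background on all 3, so transcription of these loci stays open, and no other biological explanation was tested.

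The real grouping was also set against other splits of the samples. For the Dox effect all 100 splits of the 10 arrays gave at least as many miRNAs as the real 0, which no split could miss, so this count says nothing about chance. The highest other split gave 121 and the next 8. The split with 121 kept the Dox states apart on days 7, 10 and 14 and put the day 3 pair on 1 side and the day 5 pair on the other. With day as a block it thus estimates the mean Dox difference of days 7, 10 and 14. Its spread comes from the differences within the pairs of days 3 and 5 and from how that difference varied among days 7, 10 and 14. Among the 16 swaps within days, which keep the day pairs, the highest other count was 0 too, while the count at an unadjusted p under 0.05 was 89 in the real grouping and at most 78 in the others. For the lists in the same swaps 5 of 16 gave as many as the real 7 (highest other 9), and for the interaction 3 of 16 gave as many as the real 112 miRNAs at an unadjusted p under 0.05 (highest other 122). For the lists shifted in the Dox effect, 21 of 100 splits gave as many as the real 7 (highest other 10), so chance could not be excluded. For the interaction the 16 swaps within days are too few to test chance: the real count was 0 miRNAs and the highest other 0 (all 16 gave as many), and the real count was 7 lists and the highest other 9 (8 gave as many). For the slope without Dox, 2 of 100 orders of the days gave as many as the real 66 miRNAs. They were the real order itself and its exact reverse, which gave 80. This excludes only a random order of the days, at the share of 0.05. A steady drift over the arrays, such as one along the slide column, would give the count too. For the 5 lists shifted in this slope, 25 of 100 orders gave as many (highest other 6), so there chance could not be excluded. For the slope with Dox, 5 of 100 orders gave at least the real 1 miRNA (highest other 23) and 16 gave at least its 7 lists (highest other 9), so neither excluded chance.

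The Dox difference of 7 lists changed with day by camera at the preset correlation, with median changes per day of -0.0832 for the miR-290-295 cluster, 0.164 for neuron-enriched miRNAs, 0.205 for let-7, -0.0656 for the miR-200 family, -0.0688 for the sensory cluster, -0.0181 for the Dlk1-Dio3 cluster and -0.0720 for the Sfmbt2 cluster. All had adjusted p = 0.68 with an estimated correlation.

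Single arrays stood far from the other 4 of their Dox state in 30 of 183 groups of 5 arrays (16.4%), of which 175 were of a named miRNA in 1 Dox state and 8 of a measure of the whole array. Chance gives about 1 in 20 for replicates, but these 5 arrays are days of a time course, where a trend can set the first or last day apart, and 10 of the 30 were on day 3 and 10 on day 14. The groups are not independent, and 13 of the 30 had the other 4 arrays at the floor. The values below are the gap to the nearest other array divided by the whole range, where 1 means that the other 4 arrays were all at the floor. With Dox on day 14 the gap was 1 for let-7d-3p (signal 48.7), let-7d-5p (113), let-7i-5p (100.04), miR-199a-3p (77.3), miR-215-5p (48.3) and miR-34b-3p (33.5), 0.918 for let-7g-5p, 0.721 for miR-203-3p and 0.830 for miR-302c-5p. With Dox on day 3 it was 1 for miR-126a-3p (40.1), 0.851 for miR-376c-3p and 0.761 for miR-93-5p, and with Dox on day 7 it was 1 for miR-206-3p (38.5). Without Dox on day 3 it was 0.719 for miR-291a-3p (9553, against 936 to 1796), 0.739 for miR-291a-5p, 0.924 for miR-294-5p, 0.869 for miR-295-5p, 0.726 for miR-17-5p, 0.759 for miR-494-3p and 1 for miR-34b-3p (40.2, not above background on that array). Without Dox on day 5 it was 1 for miR-466o-3p (1010.6) and miR-215-5p (35.9), 0.917 for miR-302a-5p, 0.797 for miR-669d-3p and 0.732 for miR-20a-5p, which was low there. Without Dox on day 7 it was 1 for miR-133b-3p (33.5) and miR-183-3p (46.0), 0.719 for miR-200b-3p and 0.782 for miR-7b-5p, and on day 14 it was 0.973 for miR-199a-3p (156).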

How the results depend on the processing

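The alternatives with the scanner's detection flag and without days 5 and 10, and all list tests of the interaction, were chosen only after the data were seen. Of the planned comparisons of single miRNAs and lists with an alternative, 2918 kept their side of the threshold, 95 lost a call and 63 gained one. Of the 2918, the estimate kept its sign in 2803, was at 0 in 47 and changed sign in 68, none of which had been called (0). Among called results the median changed sign, with the call lost, for the Dlk1-Dio3 list without day 14 in the slope without Dox (0.01) and the interaction (0.0014), and for the Sfmbt2 list in the interaction (0.06, miRNAs above background on all 10 arrays). The Dox effect had 32 miRNAs past the threshold after normexp and 35 with only miRNAs above background on all 10 arrays, where fewer miRNAs were tested (228), and the interaction had 9 after normexp. The slope without Dox (66) had 29 with scaling over all miRNA probes, 30 after normexp, 20 with miRNAs above background on all 10 arrays, 0 without days 5 and 10 (fewer samples) and 1 to 61 with each day pair left out (lowest without day 14, highest without day 7). The slope with Dox (1) had 2 with scaling over all miRNA probes (miR-205-5p not among them), 2 after normexp, 2 with the mean of all probes and 2 with the scanner's flag, 0 without a detection filter, 6 on log2 of day, 4 with slide as a block, 0 without days 5 and 10 and 0 with any day pair left out. List calls of the Dox effect (7) went to 3 with miRNAs above background on all 10 arrays, and to 0 with an estimated correlation and 0 with fry. Under that filter the sensory call was lost (camera adjusted p = 0.11). The neuron-enriched, let-7 and miR-34 and miR-449 lists had too few members there for a test. List calls of the slope without Dox (5) went to 2 under that filter, to 0 with an estimated correlation and to 3 with fry. The neuron-enriched and let-7 lists were again not tested under the filter. Those of the slope with Dox (7) went to 0 with an estimated correlation, 0 with fry and 2 to 7 with each day pair left out, and those of the interaction (7) to 0 and 0. The count of miRNAs differing by at least 1 log2 on day 3 (17) was 0 after normexp, 37 with the total signal per miRNA, 10 with the mean of all probes and 29 with a floor of 1. On day 5 (15) it was 6 after normexp and 8 with the mean of all probes, on day 7 (56) 29 after normexp and 104 with a floor of 1, on day 10 (134) 83 and on day 14 (134) 68 after normexp, and for MC1 (34) 12 after normexp. Except where fewer miRNAs or samples are named, the cause was not tested. Without the replicate block, with day left out of the model, the Dox effect had 0 miRNAs past the threshold by limma (34 at an unadjusted p under 0.05) and 5 lists, the let-7 and miR-34 and miR-449 lists being lost, and no other call changed. The miR-34 and miR-449 call of the Dox effect was lost in 10 of 17 settings. Signals close to the floor limit the size of every difference that starts from it, since a floored signal gives only a lower bound. Normexp was run on the median spot signal in place of the mean spot signal, which the files lack, so the planned form of it was not run.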

Other observations

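The miRNAs of the first paragraph were picked from the values, and their groups were not tested as lists.

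Of the 66 miRNAs past the threshold for the slope without Dox, 44 were on no list, out of 245 tested on no list, and all 44 rose. Of the miR-30 family, miR-30a-5p rose at 0.28 ± 0.05 log2 per day (SE, limma adjusted p = 0.0083), and miR-30c-5p, miR-30d-5p and miR-30e-5p rose at 0.21, 0.19 and 0.18, while miR-30b-5p did not pass (0.24, limma adjusted p = 0.065). miR-99a-5p and miR-100-5p rose at 0.46 and 0.36, while miR-99b-5p did not pass (0.14, limma adjusted p = 0.33). miR-181a-5p and miR-181b-5p rose at 0.33 and 0.28, miR-26a-5p and miR-26b-5p at 0.17 and 0.17, and miR-103-3p and miR-107-3p at 0.20 and 0.24. The slopes of miR-15a-5p and miR-16-5p, miRNAs known to restrain the cell cycle, were 0.17 and 0.10. Those of these that passed had limma adjusted p = 0.0031 to 0.039. miR-149-5p, miR-342-3p and miR-331-3p were higher without Dox on all 5 days, by 1.21 ± 0.22, 1.30 ± 0.35 and 1.06 ± 0.20 log2, and miR-23a-3p and miR-27a-3p, of 1 cluster, were lower on all 5 days, by -0.48 ± 0.12 and -0.44 ± 0.13. None of these 5 passed the threshold for the Dox effect (limma adjusted p = 0.16 to 0.18).

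The differences between cells without and with Dox on day 10 and day 14 correlated at 0.816 across miRNAs, those of day 7 with day 10 at 0.465, those of day 7 with day 14 at 0.439 and those of day 5 with day 7 at 0.474. Day 5 correlated with days 10 and 14 at 0.129 and 0.158, and day 3 with the later days at -0.12 to 0.16. Across miRNAs these are not independent replicates. The first principal component (44.9% of the variance) had its highest scores on the arrays without Dox of days 14 and 10, at 16.9 and 15.4, and its lowest on both day 5 arrays, at -15.2 and -14.6. On the second component (28.9%) the arrays of days 3 and 7 had negative and those of days 5, 10 and 14 positive scores.

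On the day 10 array without Dox miR-3063-3p had a signal of 1295, against at most 164 on the other Ascl1 arrays of days 5 to 14, and miR-30b-3p had 383 there against at most 42.3 on the other Ascl1 arrays. miR-376c-3p had 859.9 there and 437 with Dox on day 3. In the authors' table miR-544-3p had a value of 127811 on the day 7 array without Dox and at most 10.6 on the others, where in the scanner file 1 of its 10 spots was an outlier with a signal of 175237 and the others were not above background.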
